A study of Nothobranchius furzeri with 20 samples.

How the data were processed

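Brain RNA of male turquoise killifish (Nothobranchius furzeri, strain MZM-04/10p) was profiled by RNA sequencing in 20 libraries. The labels place 5 libraries in each of 4 groups: fish of 9 or 27 weeks given the solvent DMSO or rotenone at 1% of the LC50, the median lethal concentration. Groups were taken from the age and treatment labels. Replicate numbers were given in accession order and pair no libraries. Every library has a sample code of its own, but the labels do not state that each came from a separate fish, so p-values measure the spread between these libraries.

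Per the labels' protocols, libraries were made from total RNA with the TruSeq RNA kit, version 2. Per the submitters' processing notes, bcl2fastq 1.8.4, STAR 2.4.1d and featureCounts 1.4.6-p4 were used. The genome build, the annotation, the strand setting and any filter on reads are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical copies, could therefore not be told apart here.

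The deposited count table holds whole-number counts for 26739 genes in the 20 libraries, not normalized, of which 3724 genes had no count. Counts per library summed to between 19433958 and 24159773, so that 1 count in the smallest library corresponded to 0.051 CPM, the usual scaling of counts to the library total. No 2 libraries of a group agreed within sampling noise: the chi-square per degree of freedom, over genes with at least 20 counts in a pair, ran from 7.80 to 57.1 over the 40 pairs within groups.

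The deposited RPKM table (reads per kilobase of gene, scaled to library total) holds the same genes and libraries. Comparing it with the counts showed which library total stood behind each value. With each library's own total, 7.51% of the 431241 RPKM values above 0 were recovered within 0.0011 RPKM. With the 20 totals taken in a fixed order that moved on from row to row, as happens when a vector of totals is recycled down the columns of a matrix, 99.98% were recovered. The deposited RPKM of a gene therefore differed from the value with the library's own total by a factor between 0.804 and 1.24. Main tests used the counts, and RPKM values, deposited or recomputed with own totals, entered only as alternatives. Gene lengths were recovered from the ratio of counts to RPKM. Among tested genes their median was 2669.5 bases, and 51.6% of them were multiples of 3.

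Genes are given by identifiers of the form Nfu_g_1 and a number, and the files do not pair them with names. The RefSeq gene table used here (assembly NfurGRZ-RIMD1) matched 0 of the identifiers, so no gene could be named, no coordinates are given, and the 41 gene lists fixed before the data were examined were not tested. Identifiers are printed by a rule fixed at the same time, with changes. Its demand for a gene symbol was dropped, fewer genes were taken per direction, and genes that did not pass were not added where few passed. Among genes with an adjusted p below 0.05, a mean of at least 1 log2 CPM and no overlap between the libraries of both groups, those with the largest rise and the largest fall were taken, at most 2 in each direction. The overlap criterion does not apply to the interaction. This left 2387 genes to choose from for age in DMSO, 71 for rotenone at 27 weeks, 2 for rotenone at 9 weeks, 4 for the interaction and 4111 for age in rotenone.

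Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 19452 genes holding 99.96% of all counts. Libraries were scaled by TMM, with factors between 0.980 and 1.02. A quasi-likelihood model with 1 mean per group was fitted to all 20 libraries with robust estimation (common biological coefficient of variation 0.215). Comparisons were 27 against 9 weeks in DMSO and in rotenone, rotenone against DMSO at 27 and at 9 weeks, and the difference of the rotenone effect between the ages. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its comparison. Fold changes are log2 with the standard error implied by the test. Levels are CPM scaled by TMM, and log2 CPM used a prior count of 2.

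Covariances of log2 fold changes across genes were computed from log2 CPM. Where both fold changes used the same DMSO group, products of a library with itself were left out, which equals splitting that group in every way. Their error came from leaving out each library in turn (jackknife). The value expected of unchanged groups was simulated 50 times. The first component of differences within groups was taken from log2 CPM after subtracting each group's mean. Genes are not independent replicates, and a correlation across genes is given as a description only. A comparison of 5 against 5 libraries in an exact permutation test cannot give a p below 0.0079.

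The tests were checked on counts simulated from the means and library sizes of these data, with 67 genes changed by 1.5-fold, 67 by 2-fold and 66 by 4-fold. At 2-fold, 91.0% of changed genes were recovered for age in DMSO, 71.6% for age in rotenone, 76.1% for rotenone at 27 weeks, 86.6% for rotenone at 9 weeks and 76.1% for the interaction. At 1.5-fold the shares were 58.2%, 49.3%, 59.7%, 56.7% and 34.3% in the same order. Between 0.606% and 8.23% of the calls were false. Changed genes were drawn only from those with a mean of at least 1 CPM, and each comparison was simulated once. Counts of genes were drawn independently and with equal spread in all groups, so genes moving together within groups were not represented. Comparisons of 5 against 5 libraries shared the same simulated means and spread. Differences among their shares therefore reflect the random draw and not a difference in power. A simulated covariance of 0.08 was returned as 0.0802 with the shared libraries split and as 0.0483 without.

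Alternatives were other scaling factors, no filter or a stricter filter on low counts, 1 surrogate variable (sva 3.50.0), a fit of only the 10 libraries compared, DESeq2 1.42.0, limma-voom with quality weights and limma-trend on log2 RPKM with a pseudocount of 0.1 or 1 (limma 3.58.1), and leaving out each library. The recomputed RPKM and the fit without both 27-week DMSO libraries 1 and 4, or both 9-week rotenone libraries 1 and 3, were added after seeing the data.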

Results

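Gene expression in the brain of the turquoise killifish, a short-lived annual fish kept for the study of ageing, was measured at 9 and 27 weeks of age. Fish had received rotenone, an inhibitor of complex I of the mitochondrial respiratory chain, at 1% of its LC50, or its solvent DMSO. Each of the 4 groups held 5 libraries of male fish, with totals of 21155551 to 24045080 counts for DMSO at 9 weeks and 20611587 to 24159773 counts for rotenone at 9 weeks. At 27 weeks the totals were 21217905 to 23713285 counts for DMSO and 19433958 to 23933846 counts for rotenone. Of 26739 genes, 19452 had enough counts to be tested. The files give genes by identifiers without names.

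The ages lay apart on the first axis of variation in rotenone fish and overlapped in DMSO fish. The first principal component held 27.4% of the variance of log2 CPM, and the second 14.5%. All 10 libraries of 9 weeks lay above 0 on the first component, with means of 27.96 ± 21.94 for DMSO and 24.6 ± 19.0 for rotenone (SD, n = 5 each). All 5 rotenone libraries of 27 weeks lay between -45.9 and -27.8, with a mean of -37.7 ± 6.55. DMSO libraries of 27 weeks were more spread, from -41.1 to 12.5, with a mean of -14.9 ± 19.3.

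**Figure D1:**
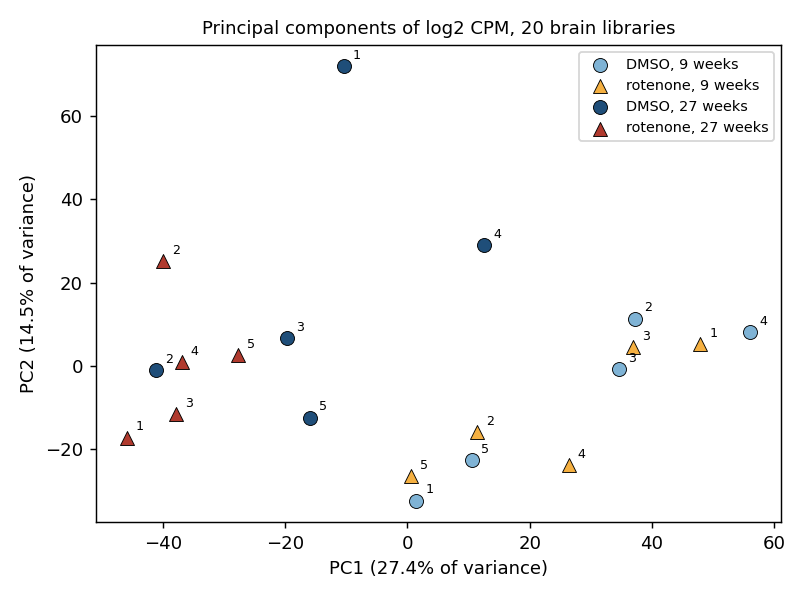
First and second principal components of log2 CPM over 19452 genes, in units of component score; each point is a library, with its replicate number, coloured by group. The rotenone libraries of 27 weeks lie between -45.9 and -27.8 on the first component, while DMSO libraries of that age range from -41.1 to 12.5.

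Some genes were present at 2 distinct levels within groups. In 97 genes, sorted log2 CPM values had a gap above 1.5 with at least 3 libraries on each side. These genes parted the 20 libraries in 66 ways, and 2 of these ways were shared by 10 genes each, against at most 4 for any other. The first set of 10 genes was high in 11 libraries and near 0 in 9, by 3.25 to 8.50 on the log2 scale, and its libraries were balanced: 3 of 5 high in every group except DMSO at 27 weeks, with 2 of 5. Nfu_g_1_014206, with the highest mean log2 CPM of the set, stood at 261 to 1702 CPM in the 11 libraries and at 0.710 to 3.85 CPM in the other 9. The second set of 10 genes was high in 13 libraries and low in 7, by 2.05 to 4.15 on the log2 scale. It was high in 2 of 5 DMSO and 3 of 5 rotenone libraries at 9 weeks, and in 3 of 5 DMSO and 5 of 5 rotenone libraries at 27 weeks. These sets were found by looking at the values, outside the rule for naming genes.

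**Figure D2:**
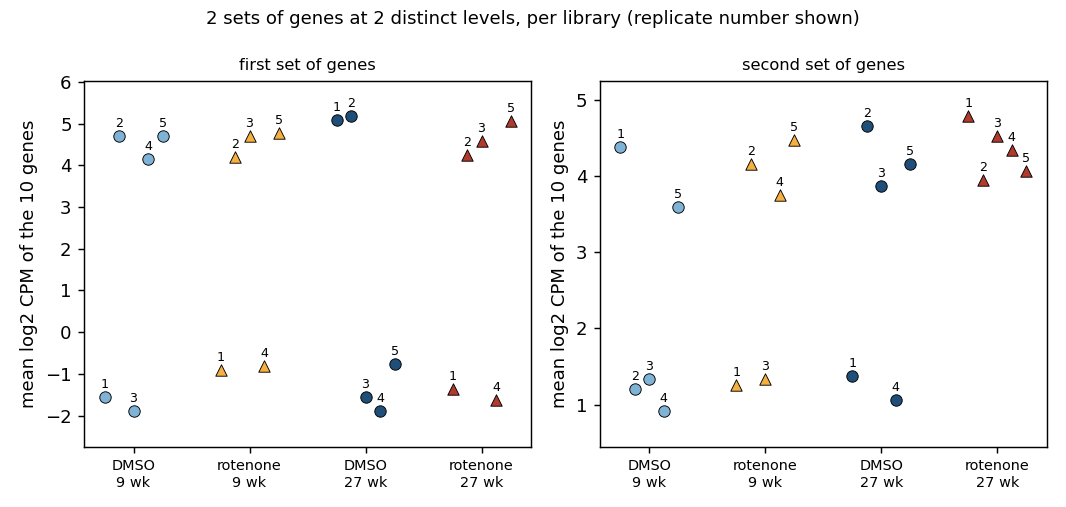
Mean log2 CPM of the 10 genes of each set, with 1 point per library, by group; numbers are replicate numbers. The first set is high in 11 libraries spread over all groups, and the second is high in 13, among them all 5 rotenone libraries of 27 weeks.

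The brain transcriptome of DMSO fish differed widely between 9 and 27 weeks. At 27 weeks 1876 genes were higher and 2694 lower, 23.5% of those tested (edgeR quasi-likelihood test, adjusted p below 0.05). Most changes were small, with a median of 0.48 on the log2 scale for genes that rose and of -0.32 for genes that fell. A change over 2-fold was seen for 284 genes that rose and 160 that fell. With library totals in place of TMM the split was more even, 2149 higher and 2263 lower. Among called genes, those in the upper tertile of mean expression fell more often than they rose (576 rose and 1439 fell), and those in the lower tertile rose more often (583 rose and 353 fell). With library totals these counts were 710 and 1202 in the upper tertile and 628 and 311 in the lower. Among the longest tertile of genes 783 rose and 839 fell, against 466 and 898 among the shortest.

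The largest rise among DMSO fish was that of Nfu_g_1_012517, from 0.0626 ± 0.0511 CPM at 9 weeks to 7.11 ± 3.87 CPM at 27 weeks (SD, n = 5 each; edgeR adjusted p = 0.0107). With 0 to 3 counts per library at 9 weeks, its fold change is not well defined. This gene was present or nearly absent from library to library: in rotenone fish it stood at 6.93 to 7.04 CPM in 3 libraries of 9 weeks and at no more than 0.131 CPM in the other 2, and at 27 weeks at 7.72 and 15.9 CPM in 2 libraries and at most 0.188 CPM in the other 3. Nfu_g_1_009837 rose from 1.17 ± 0.523 to 15.9 ± 27.07 CPM (edgeR adjusted p = 0.00354). Replicate 1 of 27 weeks stood at 64.3 CPM and the other libraries of that group at 2.28 to 5.46 CPM. Its log2 change of 3.76 ran from 1.41 to 4.04 over the alternatives. Nfu_g_1_017355 fell from 15.8 ± 2.91 to 2.88 ± 1.70 CPM, a log2 change of -2.45 ± 0.46 (SE; edgeR adjusted p = 0.00116), and fell as well in rotenone fish, by -3.15 ± 0.48 (edgeR adjusted p = 8.3e-05). Nfu_g_1_018661 fell from 3.26 ± 2.25 to 0.711 ± 0.230 CPM (edgeR adjusted p = 0.0370), a call that 6 of the 10 fits without 1 library did not make. From the deposited RPKM, 1762 genes were called for age in DMSO, against 4218 from RPKM recomputed with each library's own total.

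Age changed the brain of rotenone fish in much the same direction. In these fish 2506 genes rose and 3547 fell between 9 and 27 weeks, 31.1% of those tested, 602 of them over 2-fold. Called genes in the upper tertile of mean expression again mostly fell (1002 rose and 1637 fell). Those in the lower tertile did not share the lean to a rise seen in DMSO (560 rose and 624 fell, 589 and 602 with library totals). Among the longest tertile of genes 1104 rose and 1019 fell, against 672 and 1209 among the shortest. These libraries share none with the DMSO comparison. No batch is given in the labels, so a batch shared by all fish of the same age could not be told apart from age. Of the genes called in DMSO, 95.3% moved the same way in rotenone and 67.0% were called there in the same direction, where 77.7% of all tested genes had the same direction in both. Among genes called in both, 1022 rose in both, 2038 fell in both and 14 went opposite ways, where independent lists would give 242 and 491 in the same direction. The correlation of log2 fold changes across genes was 0.68, and their covariance 0.133 ± 0.0346 (jackknife SE).

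**Figure D3:**
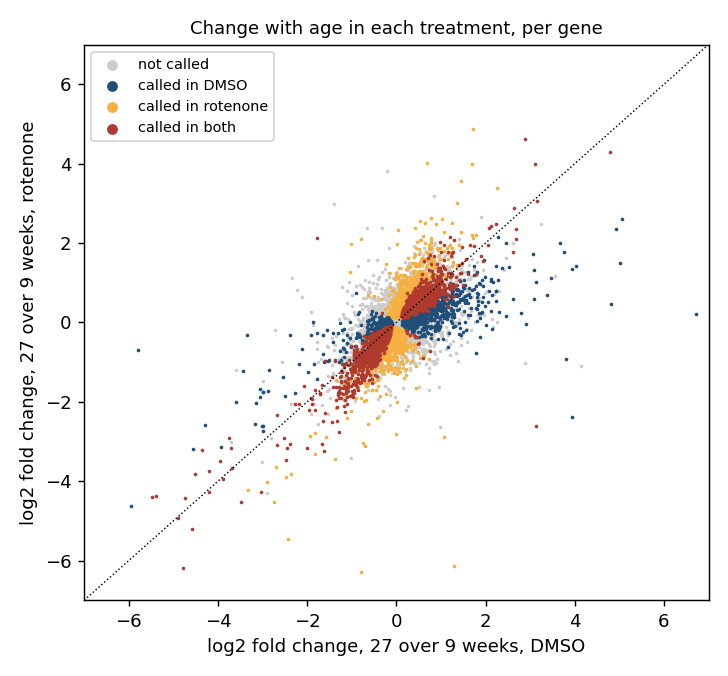
Log2 fold change from 9 to 27 weeks in DMSO fish (horizontal axis) against rotenone fish (vertical axis), 1 point per tested gene, coloured by the comparison that called it; the dotted line marks equal change. Of the 3074 genes called in both, all but 14 changed in the same direction.

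Nfu_g_1_015219 rose in rotenone fish from 0.724 ± 0.618 to 4.49 ± 1.61 CPM (SD, n = 5 each; edgeR adjusted p = 0.0294), and Nfu_g_1_010783 from 0.751 ± 0.619 to 4.59 ± 3.61 CPM (edgeR adjusted p = 0.0417). Their calls were lost in 5 and 7 of the 10 fits without 1 library. Both followed the second set of genes: Nfu_g_1_010783 stood at 0.567 CPM or more in the 13 libraries high in that set and at 0.478 CPM or less in the other 7, and Nfu_g_1_015219 at 0.392 CPM or more against 0.522 CPM or less. Without rotenone replicates 1 and 3 of 9 weeks, both low in that set, neither was called (edgeR adjusted p = 0.203 and 0.167). With 3 libraries left at 9 weeks their log2 changes were 2.06 and 2.11, against 2.61 ± 0.94 and 2.63 ± 0.88 (SE) with all 5, so the lost calls do not tell the set from age. In that fit 4067 genes were called for age in rotenone, 3839 of the 6053 among them. Nfu_g_1_023319 fell from 18.9 ± 22.5 to 0.249 ± 0.220 CPM (edgeR adjusted p = 0.00722) and Nfu_g_1_015191 from 25.09 ± 19.21 to 1.09 ± 0.540 CPM (edgeR adjusted p = 0.00142). Both fell in DMSO fish too, by -4.80 ± 1.37 and -3.48 ± 0.91 on the log2 scale (SE; edgeR adjusted p = 0.0172 and 0.0102). The variance of fold changes across genes, corrected for the spread between libraries, was 0.0860 ± 0.0347 in DMSO and 0.179 ± 0.0407 in rotenone (jackknife SE). Their difference, 0.0928 ± 0.0535, lay within 2 errors of 0.

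Rotenone changed far fewer genes than age did. At 27 weeks 29 genes were higher and 47 lower in rotenone than in DMSO fish, 0.391% of those tested. The largest rise was that of Nfu_g_1_020882, from 27.0 ± 10.4 CPM in DMSO to 81.4 ± 11.97 CPM in rotenone (SD, n = 5 each), 3.01-fold, with a log2 change of 1.59 ± 0.25 (SE; edgeR adjusted p = 0.00488). Nfu_g_1_010257 rose from 13.6 ± 1.16 to 30.0 ± 2.20 CPM, 2.21-fold (edgeR adjusted p = 0.000516). At 9 weeks this gene stood at 13.3 ± 1.59 CPM in DMSO and 13.4 ± 3.68 CPM in rotenone fish, a log2 difference of 0.01 ± 0.14 (SE). The difference between the ages, 1.13 ± 0.20 on the log2 scale, did not pass the test (edgeR adjusted p = 0.0523).

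Among genes that fell at 27 weeks, Nfu_g_1_010469 went from 11.3 ± 3.34 CPM in DMSO to 3.39 ± 0.908 CPM in rotenone, a log2 change of -1.73 ± 0.21 (SE; edgeR adjusted p = 0.000443). Nfu_g_1_006237 went from 5.17 ± 4.65 to 1.23 ± 0.346 CPM (edgeR adjusted p = 0.0257). With age in DMSO fish this gene had risen from 1.41 ± 0.231 CPM (edgeR adjusted p = 0.00249), and its 27-week mean there included 13.3 CPM in replicate 1. Calls for the other 3 of these genes held in all 22 alternatives, and that for Nfu_g_1_006237 in 16.

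**Figure D4:**
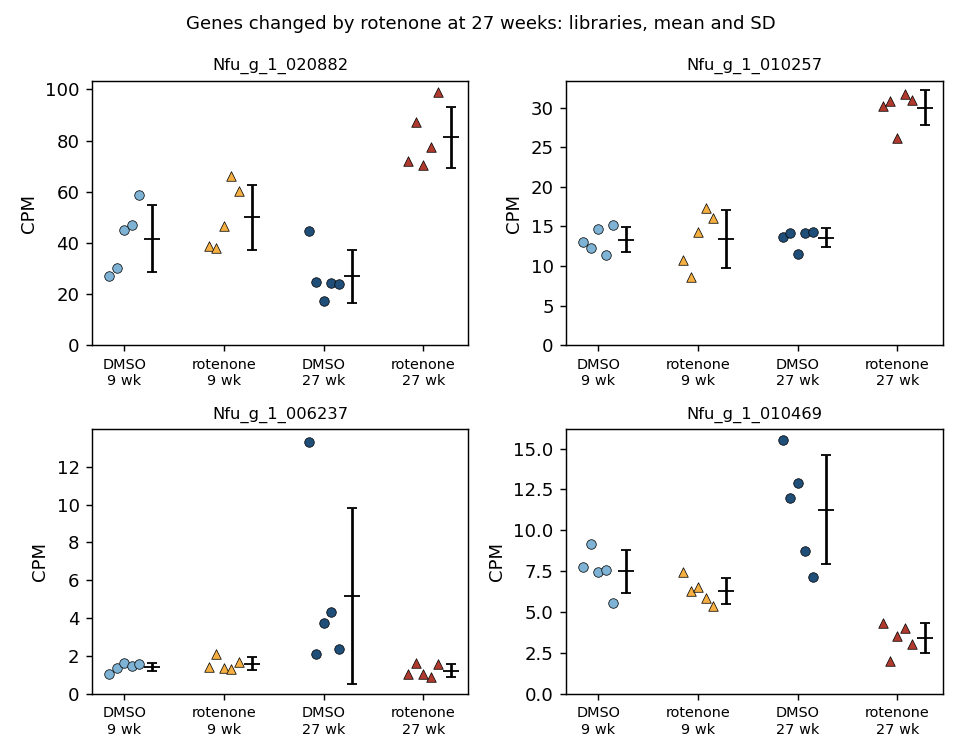
CPM (vertical axes, from 0) of the 2 genes with the largest rise (upper panels) and the 2 with the largest fall (lower panels) under rotenone at 27 weeks; points are libraries, and bars give mean and SD of 5 libraries. Nfu_g_1_010257 is at 30.0 ± 2.20 CPM in rotenone fish of 27 weeks and at 13.3 to 13.6 CPM on average in the other groups.

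The number of genes called for rotenone at 27 weeks moved by over 1.5 times when 1 of 7 of the 10 libraries was left out. None of the 76 genes changed direction in these fits. At least 71 of them had no overlap between the groups, so leaving out libraries could hardly reverse them. A kept direction is therefore no evidence here. The number was 266 without DMSO replicate 1, 142 higher and 124 lower with rotenone, with all 76 genes still called. It was 27 to 44 without DMSO replicate 3 or 4 or rotenone replicate 1, 2, 3 or 4. Without DMSO replicates 1 and 4, the 2 libraries of that age low in the second set of genes, 148 genes were called, 88 higher and 60 lower with rotenone, 48 of the 76 among them, and all 76 kept their direction. An unadjusted p below 0.05 was seen for 2810 genes where chance gives 973. The corrected variance of fold changes was 0.0284 ± 0.0334 (jackknife SE), within 1 error of 0. Across genes, which are not independent, the fold changes had a correlation of 0.551 with the first component of differences within groups, and of 0.526 with that component taken from the 9-week libraries alone. The sign of the component was set to make both positive, so only their size can be read. With library totals in place of TMM the calls were 32 higher and 96 lower, and DESeq2 called 481 genes.

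At 9 weeks 5 genes were called between rotenone and DMSO, 4 higher and 1 lower with rotenone, a number that 6 of 100 splits of these libraries reached, the real one included. The corrected variance of fold changes was -0.0143 ± 0.0214 (jackknife SE). Nfu_g_1_013232 rose from 10.4 ± 1.39 CPM in DMSO to 20.0 ± 4.69 CPM in rotenone (SD, n = 5 each), 1.92-fold (edgeR adjusted p = 0.0311). Nfu_g_1_001261 fell from 69.4 ± 3.78 to 55.0 ± 1.04 CPM, a log2 change of -0.33 ± 0.05 (SE; edgeR adjusted p = 0.0198). These calls were lost in 8 and 7 of the 10 fits without 1 library. The other 3 genes, which did not meet the rule for printing, rose from 0.703 to 2.43, from 13.6 to 25.8 and from 69.1 to 114.0 CPM. None of the 5 was called at 27 weeks, where 4 had the same direction. Without DMSO replicate 5 the count was 24 and without rotenone replicate 3 it was 12, while leaving out any other library gave 0 to 3. An unadjusted p below 0.05 was seen for 1360 genes where chance gives 973, and DESeq2 called 91.

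Effects of rotenone at the 2 ages could be compared directly, since they share no library. Of the 76 genes called at 27 weeks, 51 had the same direction at 9 weeks, 0 were called there over all genes and 11 were called when adjusted over these 76 genes alone, a list chosen on the 27-week libraries. At 9 weeks the median log2 difference was 0.10 for genes that rose at 27 weeks and -0.03 for those that fell. Over all genes the covariance was 0.00774 ± 0.0223 (jackknife SE) with a correlation of 0.112 across genes, and 51.7% of genes had the same direction.

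A test of the difference between the ages called 4 genes. Of these, 3 were also called as lower with rotenone at 27 weeks and 0 at 9 weeks, and the log2 differences lay between -0.92 and -0.22 at 27 weeks and between 0.03 and 0.40 at 9 weeks. The corrected variance of these effects across genes was -0.00138 ± 0.0469 (jackknife SE). Nfu_g_1_018392 fell at 27 weeks from 18.4 ± 2.94 CPM in DMSO to 9.72 ± 1.16 CPM in rotenone (SD, n = 5 each), and at 9 weeks stood at 26.8 ± 1.62 and 27.8 ± 2.59 CPM. The log2 effects differed by -0.97 ± 0.15 (SE; edgeR adjusted p = 0.0315). Nfu_g_1_020462 stood at 7.402 ± 0.880 and 5.18 ± 0.826 CPM at 27 weeks and at 14.4 ± 1.40 and 19.1 ± 1.45 CPM at 9 weeks, a difference of -0.92 ± 0.15 (edgeR adjusted p = 0.0472). Both genes also fell with age in DMSO, by -0.54 ± 0.10 and -0.96 ± 0.11, and by -1.52 ± 0.11 and -1.88 ± 0.11 in rotenone (SE). Their calls for this difference were lost in 10 and 14 of the 20 fits without 1 library. Leaving out DMSO replicate 1 of 27 weeks gave 34 genes, whereas 11 other libraries, each left out in turn, gave 0 or 1. DESeq2 called 150 genes for this difference, and 1947 had an unadjusted edgeR p below 0.05.

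Whether rotenone moved genes against or along with age was asked across all genes. Both fold changes use the DMSO libraries of 27 weeks, so chance alone gives a negative relation. In groups simulated without any change with age or rotenone, the correlation was -0.50 and the covariance -0.0328. Genes here did change with age, which widens their fold changes, so only the covariances are set side by side. The observed correlation was -0.02 and the covariance -0.00262, which is 0.0302 above the simulated value. With shared libraries split, the covariance was 0.0353 ± 0.0244 (jackknife SE), and an interval of 2 errors ran from -0.0136 to 0.0841. The correlation with the DMSO libraries split averaged 0.201 over 20 ways to split them, from -0.0205 to 0.391. For rotenone at 9 weeks the observed correlation with age was 0.263 and the covariance 0.0245, against a simulated covariance of 0.0329. The split covariance there was -0.0118 ± 0.0217. Neither split covariance differed from 0 by more than 2 errors.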

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

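Tests of why libraries of 27 weeks differed in spread were chosen after the result was seen for both explanations that leave out DMSO libraries, and before it for the explanation by low counts.

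In 92 groups of 5 libraries, 28 for library measures and 64 for the identifiers printed, the farthest library was compared with its neighbour. In 15 of them its gap exceeded 0.71 of the whole range, where about 4.6 would arise among independent normal values, at 1 in 20 groups. Printed genes were chosen for extreme fold changes, which a far library can help produce, and they share libraries. The number therefore tests nothing. The number of genes with a count was 21427 in DMSO replicate 4 of 27 weeks and 21600 in the nearest library. Other cases were values of printed genes. DMSO replicate 1 of 27 weeks was far from the rest for 3 of them: Nfu_g_1_009837 at 64.3 CPM against 5.46 in the nearest library, Nfu_g_1_020882 at 44.7 CPM against 24.8, and Nfu_g_1_006237 at 13.3 CPM against 4.31. DMSO replicate 1 of 9 weeks was far for Nfu_g_1_023319 at 120.2 CPM, Nfu_g_1_015191 at 43.9 CPM and Nfu_g_1_010783 at 4.32 CPM. DMSO replicate 4 of 27 weeks was far for Nfu_g_1_023319 at 4.36 CPM and Nfu_g_1_015191 at 2.73 CPM. In the same group Nfu_g_1_012517 stood at 0.296 CPM in replicate 5 against 8.11 in the nearest library, Nfu_g_1_010783 at 9.45 CPM in replicate 2 and Nfu_g_1_010257 at 11.6 CPM in replicate 3. Among rotenone libraries of 27 weeks, Nfu_g_1_018661 stood at 6.13 CPM and Nfu_g_1_010257 at 26.14 CPM in replicate 3, and Nfu_g_1_017355 at 4.03 CPM in replicate 5.

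The test of the difference itself (edgeR) called 4 genes for an effect of rotenone that differed between the ages. In 8 of the 20 fits without 1 library it called 0, with 1619 to 1936 genes at an unadjusted edgeR p below 0.05. Chance could not be excluded for these calls. Effects at 27 weeks minus those at 9 weeks were -0.97 for Nfu_g_1_018392 and -0.92 for Nfu_g_1_020462 on the log2 scale, and -0.90 and -0.55 for both genes not named by the rule.

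At 27 weeks the rotenone libraries lay closer together than the DMSO libraries. The root mean squared deviation from the group mean was 0.337 log2 CPM in rotenone and 0.437 in DMSO, a ratio of 0.772, and at 9 weeks the ratio was 0.941. An exact two-sided permutation test over 252 arrangements gave p = 0.119 at 27 weeks and p = 0.381 at 9 weeks (adjusted over both 0.238 and 0.381), so neither difference passed 0.05. Counting noise in low genes is argued against by a ratio of 0.673 among the 6809 genes above 5 log2 CPM (0.621 to 0.787 as 1 library was left out). Without DMSO replicate 1 the ratio was 0.865 (0.793 to 0.951 as 1 more library was left out), and without both DMSO libraries low in the second set of genes 0.951 (0.86 to 1.09), the highest of the 10 ways to leave out 2 DMSO libraries. These ranges are too wide to decide, so these libraries may or may not carry the difference, and an effect of rotenone on the spread stays open as well.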

How the results depend on the processing

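Alternatives were fixed before the data were examined, except for RPKM recomputed with own totals, the fits without DMSO replicates 1 and 4 of 27 weeks or rotenone replicates 1 and 3 of 9 weeks and the covariance between both age comparisons, which were chosen after seeing the data. Counts of genes for age stayed within 1.5 times in all alternatives except the deposited RPKM, which gave 1762 and 1781 genes for age in DMSO with pseudocounts of 0.1 and 1 (4570 from the counts), and 3749 and 3741 for age in rotenone (6053). RPKM recomputed with own totals called 4218 for age in DMSO, 2.39 times as many, with 1756 of the 1762 among them, which points to the totals as the cause. From the deposited RPKM 27 and 26 genes were called for rotenone at 27 weeks, 3 and 3 at 9 weeks, and 0 and 0 for the interaction by limma-trend, where 1124 genes had an unadjusted p below 0.05 (edgeR: 1947). For rotenone at 27 weeks (76) the count was 128 with library totals (32 higher and 96 lower against 29 and 47), 128 with the stricter filter, 21 with only the 10 libraries compared, 481 with DESeq2 (no adjusted p for 9968 of 26739 genes), 429 with limma-voom, 136 with recomputed RPKM and 148 without DMSO replicates 1 and 4. For rotenone at 9 weeks (5) it was 8 with 1 surrogate variable, 1 with only the 10 libraries compared, 91 with DESeq2 and 13 without rotenone replicates 1 and 3. For the interaction (4) it was 10 with the stricter filter, 150 with DESeq2 and 18 with limma-voom; with library totals 1 gene was higher and 5 lower. With 10 libraries the spread is estimated from fewer values; otherwise the cause was not tested.

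Leaving out 1 library gave 3516 to 4631 genes for age in DMSO, 4989 to 6052 for age in rotenone, 27 to 266 for rotenone at 27 weeks, 0 to 24 for rotenone at 9 weeks and 0 to 34 for the interaction. For rotenone at 27 weeks it was 266 without DMSO replicate 1, 43 and 41 without DMSO replicates 3 and 4, and 29, 44, 35 and 27 without rotenone replicates 1 to 4. For rotenone at 9 weeks it was 24 without DMSO replicate 5, 12 without rotenone replicate 3, 3 without DMSO replicate 1 and 0 or 1 without each of the others (at 0, edgeR gave 1135 to 1604 genes an unadjusted p below 0.05). For the interaction it was 34, 8 and 13 without DMSO replicates 1, 2 and 5 of 27 weeks, 8 and 7 without rotenone replicates 4 and 5 of 9 weeks, and 0 or 1 without DMSO replicates 3 and 4 of 27 weeks, DMSO replicates 1, 2, 3 and 5 of 9 weeks, rotenone replicates 2, 3 and 4 of 27 weeks and rotenone replicates 1 and 2 of 9 weeks (at 0, 1619 to 1936 unadjusted).

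The covariance of rotenone at 27 weeks with age was -0.00262 and that of rotenone at 9 weeks 0.0245 when shared DMSO libraries were not split, which adds the chance covariance. Split, they ran from 0.0227 to 0.0455 and from -0.0197 to 0.00526 as 1 library was left out; the latter turned positive without DMSO replicate 1 of 9 weeks. The covariance of rotenone at both ages ran from -0.00272, without DMSO replicate 4 of 9 weeks, to 0.0184, and that of age in both treatments from 0.114 to 0.150. Genes named by the rule kept their direction in each alternative run for their own comparison. Except for the interaction, the rule asked for no overlap between the groups in these same libraries. A reversal was therefore hardly possible, and the kept directions are no separate evidence. No paired analysis was possible because replicate numbers follow accession order only. The 41 gene lists and their alternatives were not run, for want of gene names. Depth was not varied. In counts simulated with independent genes and equal spread in all groups, 59.7% of 1.5-fold changes were found for rotenone at 27 weeks.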

Other observations

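All tests of the sets of genes were chosen after the result was seen; splits of the libraries were planned before. The test of gene length and age, and the correlations with differences within groups, were chosen after values had been seen. The 3 tests of rotenone at 27 weeks and age were planned before, but were run only after related values had been seen.

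The brain libraries differed within groups by sets of genes that rose or fell together. In all, 796 genes separated the 13 libraries high in the second set from the 7 that were low, with no overlap, and 777 of them were higher in the 13. A random division of that shape would separate 0.50 genes on average, but the libraries here were divided by their values, so the number describes the extent of the pattern and tests nothing. The gene of the set with the largest gap, Nfu_g_1_020841, stood at 56.6 to 242 CPM in the 13 libraries and at 4.88 to 10.1 CPM in DMSO replicates 2, 3 and 4 and rotenone replicates 1 and 3 of 9 weeks and DMSO replicates 1 and 4 of 27 weeks. The second set depends on the gap chosen. Gaps of 1.5, 2 and 3 on the log2 scale were tried before 1.5 was used; above 2 the second set kept 2 of its 10 genes and the first kept 9, and above 3 they kept 0 and 7. No sequencing batch is given in the labels, and whether these libraries differ in dissection, time of day or parentage is not given either.

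The first set was more sharply divided. Its 10 genes together took 808 to 2610 CPM in 11 libraries and at most 11.3 CPM in the other 9. Altogether 30 genes separated these libraries without overlap, and all 30 were higher in the 11. Age or rotenone as the source is argued against, since 4 of the 4 groups hold libraries of both kinds. Tissue of another kind, kept in some dissections and absent from others, is a candidate explanation. Its genes should then rise and fall together among the 11 libraries, and the mean correlation between them there was 0.149 (0.111 to 0.193 as 1 library was left out), below the 0.5 asked for and above 0, so that this source can be neither supported nor excluded. A difference in genotype or physiological state stays open and was not tested, and no cell type could be examined without gene names. The surrogate variable, estimated from all tested genes, had values of 0.141 or more in the same 11 libraries and of -0.213 or less in the other 9. With it in the model, counts of called genes were 4640 for age in DMSO and 85 for rotenone at 27 weeks.

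Other splits of the same libraries were refitted to see whether other groupings give as many genes. Of 100 splits of the 10 libraries drawn from the 126 possible, the real one included, 1 gave 4570 genes or more for age in DMSO. The highest of the others gave 2406. A share of 0.01 is the smallest that 100 splits can give, so it makes a chance division unlikely without excluding it. The split with 2406 genes differed from the real one by exchanging DMSO replicate 4 of 27 weeks with replicate 1 of 9 weeks. The next, with 1545 genes, divided the libraries as the second set of genes does; that set was found from the same values, so this is no separate evidence for it. For age in rotenone 1 of 100 splits reached 6053 genes, with 2 as the highest other. For rotenone at 27 weeks 1 of 100 reached 76, with 34 as the highest other. The same limit holds for both. For rotenone at 27 weeks the corrected variance of fold changes, 0.0284 ± 0.0334 (jackknife SE), was also within 1 error of 0. For the interaction 2 of 100 splits of treatment within age reached 4 genes, the real one included, with 9 as the highest other. This is under the 0.05 asked for. Such splits assume no rotenone effect at either age, not an equal effect at both, so they cannot exclude chance for the interaction. In 8 of the 20 fits without 1 library, 0 genes were called (edgeR, 1619 to 1936 with an unadjusted p below 0.05). For rotenone at 9 weeks 6 of 100 splits reached 5 genes, the highest other giving 25, so chance cannot be excluded.

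The covariance of rotenone at 27 weeks with age, 0.0353 ± 0.0244, did not differ from 0 by more than 2 errors, so the tests below concern a relation that is itself not established. Without 1 DMSO library of 27 weeks its lowest value was 0.0227, above 0 by less than 1 error, which leaves a single library open. Gene length is argued against, since 96.5% ± 4.48 (jackknife SE) of the covariance was left after the trend with length and mean expression was removed. With the first component of differences within groups removed, 49.9% ± 49.4 was left, which decides nothing. That component had a correlation across genes of 0.551 with the effect of rotenone at 27 weeks, and of 0.526 when taken from the 9-week libraries alone, which the 27-week comparison does not use. Its sign was set to make both of these positive, so only their size can be read. The correlation was 0.353 for age in rotenone, 0.376 for the interaction, 0.129 for rotenone at 9 weeks and 0.0901 for age in DMSO. No value expected of unchanged groups was computed. The component followed the second set of genes. In groups holding both kinds, its scores were 8.05 or more in libraries high in that set and -10.2 or less in low ones. At 27 weeks that set was high in 5 of 5 rotenone and 3 of 5 DMSO libraries. Differences between samples that exist apart from rotenone may therefore make up part of the 27-week fold changes. Of the 796 genes that separated the libraries of that set without overlap, 0 were called for rotenone at 27 weeks. For age, 3 were called in DMSO and 102 in rotenone. Such genes vary within the DMSO group of 27 weeks, which works against a call. The genes called for rotenone at 27 weeks are thus not among these 796, which leaves the fold changes over all genes open. The slope of log2 CPM on log2 gene length changed with age by 0.0106 ± 0.0099 in DMSO and by 0.0178 ± 0.00552 in rotenone (SE). In rotenone fish, longer genes therefore did not fall relative to shorter ones, while in DMSO fish the change was close to its error.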
